A study of Arabidopsis with 27 samples.

How the data were processed

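RNA was measured in 27 systemic rosette leaf samples of Arabidopsis thaliana, in 9 groups of 3: 3 genotypes (wild-type Col-0 and the double mutants glr3.3glr3.6 and p2k1p2k2) by 3 treatments of a local leaf (mock buffer, eATP and L-Glu). Per the labels, each replicate is a pool from 8 plants of 4 weeks, and the systemic leaf was frozen 30 min after the local leaf was treated. The labels call the first treatment extracellular ATP in the sample titles, and give 300 µM of its analogue βγmeATP as the treatment; it is written eATP here. L-Glu was given at 100 mM. Every library's group was taken from its label.

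The deposited values are FPKM (mapped fragments scaled to transcript length and library total) for 32824 genes. The authors list Trim Galore 0.6.7, FastQC 0.11.9, HISAT2 2.2.1, SAMtools 1.19, Cufflinks 2.2.1, Cuffdiff 2.2.1 and the genome build TAIR10, without the order or settings of each. Whether the FPKM were scaled further between libraries is not stated. FPKM carry no read counts, so the depth of each library is unknown, and no counting interval or detection limit was computed. Identifiers of 32539 genes matched the reference gene table and 285 did not. No coordinates are given, since the build of that table differs from the one the authors name.

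FPKM were analysed as log2(FPKM + 1), with a pseudocount of 1, for the 16577 genes with a mean of at least 1 FPKM over the 27 libraries. A linear model with 1 mean per group was fitted to all 27 libraries in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), which left 18 residual degrees of freedom and gave 3.09 prior degrees of freedom. All limma tests were two-sided. The 15 comparisons were eATP and L-Glu against mock in each genotype, eATP against L-Glu in each genotype, each mutant mock against Col-0 mock, and the difference between each mutant's response and that of Col-0. P values were adjusted by Benjamini-Hochberg over the genes of 1 comparison, and a gene was called at an adjusted p under 0.05. The p measures the spread between pooled repeats, not between plants.

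A total of 21 gene lists with 328 members was fixed before the data were examined, from textbook knowledge of leaf signalling and cell types. Of these members, 1 was dropped because its symbol belonged to another locus. The lists were receptors, ROS and high-light acclimation, calcium and touch, jasmonate, salicylate, early immune signalling, ethylene, abscisate with drought and cold, heat shock, glutamate and nitrogen metabolism, photosynthesis, morning and evening circadian clock, cell wall and growth, and markers of guard cells, epidermis and trichomes, vasculature, shoot apex and dividing cells, root, flower and senescence. The 18 lists with at least 5 tested members were tested with camera, which compares the genes of a list with all other genes, at its preset correlation of 0.01 between genes. Its p values were adjusted over the 270 tests, and the same tests were repeated with the correlation estimated from the residuals. Members were also counted with p adjusted over the list alone.

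The genes named were set by a rule fixed before the data were examined. It takes GLR3.3, GLR3.6, P2K1 and P2K2 in every group. For each comparison of a treatment with mock, or of a mutant mock with Col-0 mock, it takes the 10 highest and 10 lowest changes among called genes whose groups do not overlap, and 5 of each for the other comparisons. Where fewer than 5 genes pass, it adds the 5 genes with the smallest p, as genes that do not pass. For each list described it takes up to 4 members with the smallest p.

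Replicate numbers were checked for pairing: within each group the mean was removed, and libraries with the same number were correlated. Where the numbers paired the samples of a comparison, the fit with the number as a block within genotype is given. The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM (11721 genes), quantile normalization, median-of-ratios scaling, a block on the replicate number within genotype, library weights, a fit of only the libraries compared, and leaving out each library in turn. A block across genotypes, and effects of genotype or treatment averaged over the other factor, were added after the data were seen. For each comparison the 3 against 3 libraries were regrouped in all 10 ways, and for the responses and averaged effects in 100 drawn ways.

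The fit was tested on 27 simulated libraries with each gene's own level, spread and replicate-number effect, with 200 of 16577 genes, all with a typical level above 5 FPKM, changed in the Col-0 eATP group. It recovered 24.3% of the genes changed 1.5-fold, 78.7% of those changed 2-fold and 98.5% of those changed 4-fold, with 1 false call. With the block within genotype these were 56.8%, 93.4% and 100%, with 7 false calls. The planned description of genes called in Col-0 within the mutants was not run, because 0 genes were called in Col-0 by limma. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.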

Results

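Transcript levels were measured by RNA sequencing in leaves that had not been treated themselves, 30 min after another leaf of the same rosette received buffer (mock), extracellular ATP (eATP, given per the labels as the analogue βγmeATP) or L-glutamate (L-Glu). The plants were wild-type Col-0 and 2 double mutants. The glr3.3glr3.6 line is named for 2 glutamate receptor-like channels, and p2k1p2k2 for 2 lectin receptor kinases that bind extracellular ATP. Each of the 9 groups held 3 libraries, each from a pool of 8 plants. Libraries are named here by group and replicate number (Col-0 mock 1). The values are FPKM, so the depth of a library is unknown. Summed FPKM ran from 740955 to 822758 per library, and 21042 to 21843 genes were above 0. Replicates of a group correlated across genes at 0.939 to 0.974.

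Libraries also differed by replicate number. The first principal component held 24.4% of the variance, with the 9 libraries of number 1 at or below -12.3 and all others at or above 0.981. PR1, a defence gene driven by salicylate, averaged 60.2 FPKM in number 1, 14.2 in number 2 and 1.46 in number 3. The labels do not say what the numbers share. List medians are therefore also given within numbers 1, 2 and 3, in that order, each from 1 library per group.

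**Figure D1:**
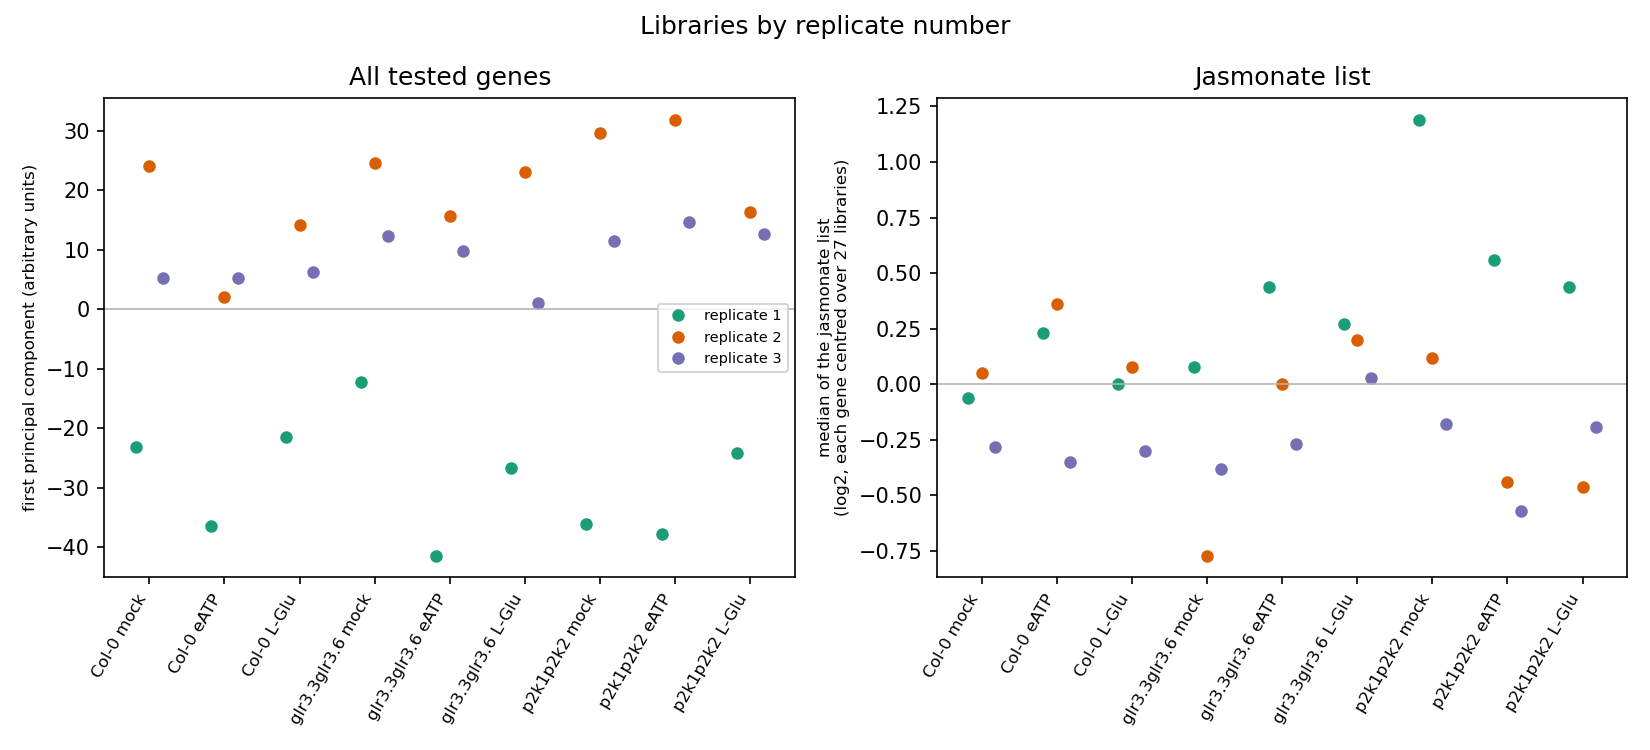
Each of the 27 libraries (points, coloured by replicate number) by group, on the first principal component of all tested genes (left, arbitrary units) and as the median of the jasmonate list (right, log2 of FPKM + 1, each gene centred over the 27 libraries). On the first component the libraries of number 1 lie at or below -12.3 and the others at or above 0.981.

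The genes for which the mutants are named were measured in every group. In the libraries labelled glr3.3glr3.6, GLR3.6 (AT3G51480) stood at 95.9 ± 22.1 FPKM (SD, n = 9), against 1.06 ± 0.217 in Col-0 and 1.12 ± 0.242 in p2k1p2k2. GLR3.3 (AT1G42540) stood at 7 ± 0.689 FPKM there, against 3.91 ± 0.533 in Col-0 and 4.11 ± 0.498 in p2k1p2k2. In the libraries labelled p2k1p2k2, P2K2 (AT3G45430) stood at 16.9 ± 8.76 FPKM, against 0.551 ± 0.201 in Col-0 and 0.472 ± 0.125 in glr3.3glr3.6. P2K1 (AT5G60300), also known as DORN1, stood at 6.4 ± 2.57 FPKM there, against 1.6 ± 0.364 in Col-0 and 1.74 ± 0.38 in glr3.3glr3.6. The FPKM of all 4 genes was thus higher in the line named for their loss; FPKM per gene does not show which part of a transcript was read. Whether these lines lack the 4 gene products is therefore not shown here, and every mutant comparison below is one of libraries labelled so. Within each genotype, none of the 4 genes was called for a treatment by limma.

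**Figure D2:**
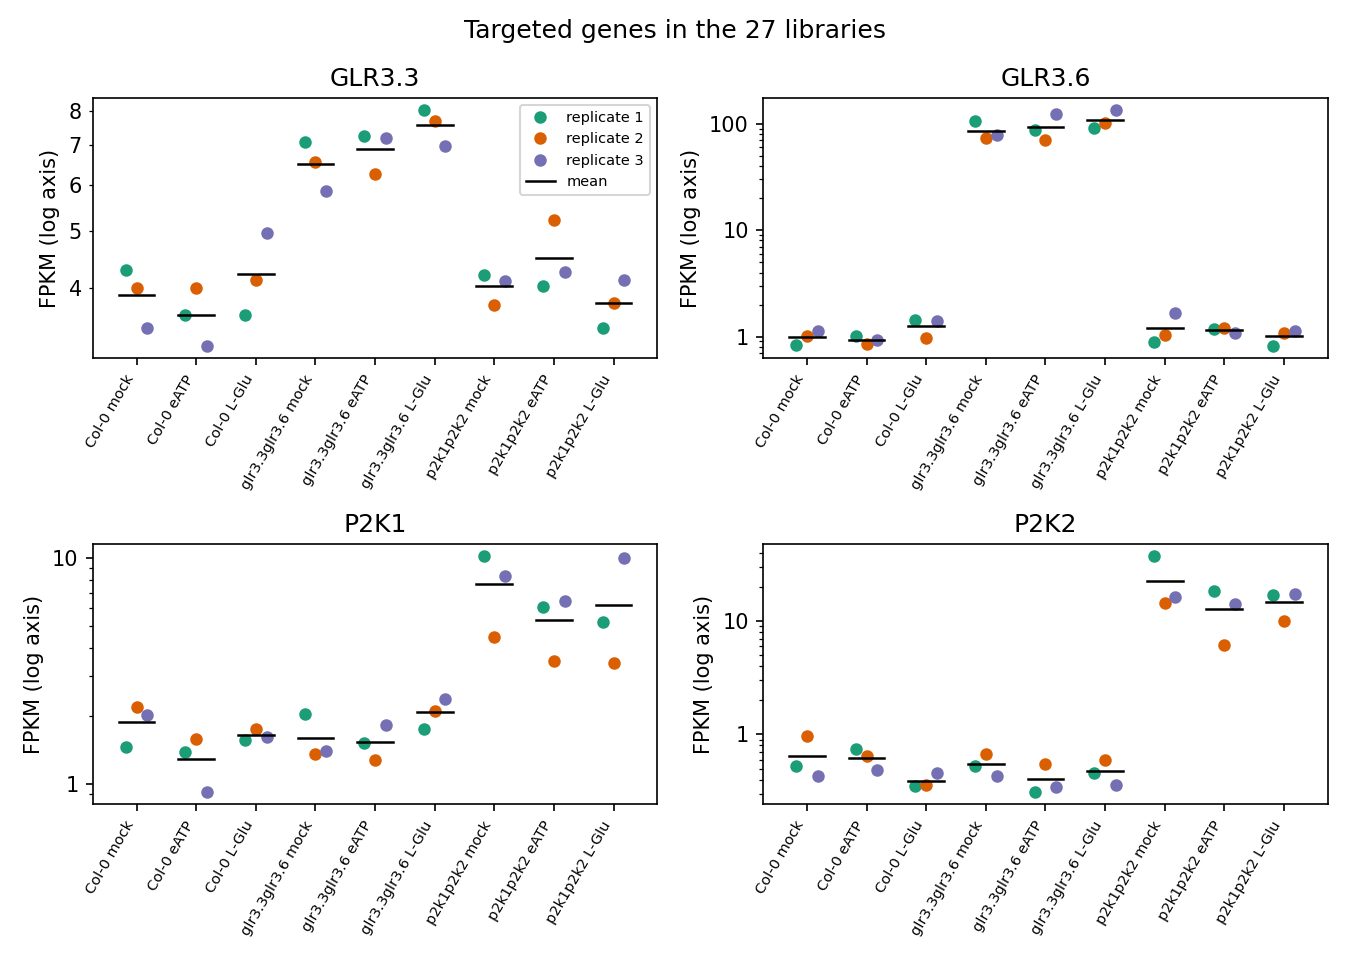
FPKM (log axis) of GLR3.3, GLR3.6, P2K1 and P2K2 in each of the 27 libraries (points, coloured by replicate number) by group, with the group mean as a line. The lowest GLR3.6 value in glr3.3glr3.6 was 70.5 against at most 1.67 elsewhere, and the lowest P2K2 value in p2k1p2k2 was 6.15 against at most 0.967 elsewhere.

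The first genotype comparison asked how glr3.3glr3.6 leaves differ from Col-0 without a stimulus. Libraries labelled glr3.3glr3.6 mock held 7 genes higher and 1 lower than Col-0 mock (limma; 358 genes at an unadjusted p under 0.05). GLR3.6 rose by 5.43 ± 0.18 on the log2 scale (SE; 85.6 ± 17.7 against 0.987 ± 0.149 FPKM, SD, n = 3, adjusted p = 1.22e-14). TMT3 (AT3G51490), a sugar transporter of the vacuole membrane, rose (27.6 ± 12.8 against 0.106 ± 0.0226 FPKM, adjusted p = 1.74e-10). PMI1 (AT1G42550), needed for chloroplast movement, rose by 1.29 (73.4 ± 13.5 against 29.6 ± 5.79 FPKM, adjusted p = 0.00302). MRD1 (AT1G53480, 4.03), AT1G75945 (4.01), AT1G07887 (11.2 ± 1 against 0.24 ± 0.204 FPKM) and AT5G46295 (2.76) rose as well, from at most 3.14 ± 0.591 FPKM to between 11.2 ± 1 and 26.9 ± 3.21. AT3G56210 was the gene that fell (-0.74 ± 0.12, 9.04 ± 1.75 against 15.7 ± 2.09 FPKM, adjusted p = 0.00792). In all 8 the groups did not overlap, which chance gives for 10% of genes. GLR3.3 did not pass (0.62, 6.51 ± 0.635 against 3.9 ± 0.441 FPKM, adjusted p = 0.0509), though it was called with library weights and with the number as a block across genotypes (adjusted p = 0.0419). Blocking within genotype called 13 genes, all 8 among them, with AT5G58570 (-1.02, adjusted p = 0.00119), PMSR2 (-0.64, 0.00119), SRC2 (-0.61, 0.0128), KCS12 (0.77, 0.0216) and RABA6b (-0.67, 0.0422). That block does not pair the 2 genotypes and leaves the spread between numbers out of the SE. The block across genotypes called 12 genes, all 8 among them. Of the genes added within genotype, it called only SRC2 (adjusted p = 0.0074). AT3G56210 lost its call without Col-0 mock 1 (adjusted p = 0.113), Col-0 mock 2 (0.087) or glr3.3glr3.6 mock 2 (0.101). PMI1 and AT3G56210 did not pass when only these 6 libraries were fitted, nor AT1G07887 at a pseudocount of 0.1.

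Among the lists, 4 differed between these mocks. The 7 epidermis and trichome markers were all higher (median log2 difference 0.29, by number 0.49, 0.25 and 0.19, adjusted p = 0.00167, adjusted p = 0.724 with an estimated correlation), led by FDH (243 ± 6.92 against 189 ± 13.5 FPKM), ATML1, PDF2 and CER6. The jasmonate list was lower (median -0.33, by number 0.08, -0.88 and -0.17, 19 of 24 negative, adjusted p = 0.00458, adjusted p = 0.927 with an estimated correlation), with the synthesis genes OPR3 (-0.72), LOX3 (-0.71), AOC3 (-0.53) and AOS (-0.43). The list of abscisate, drought and cold genes was lower too (median -0.15, by number -0.21, -0.37 and -0.02, 17 of 18 negative, adjusted p = 0.0185, adjusted p = 0.724 with an estimated correlation), with COR15A at 325 ± 51.6 against 451 ± 1.15 FPKM, and COR15B, COR47 and KIN1 between -0.55 and -0.35. The receptors list was called higher (adjusted p = 0.00458, adjusted p = 0.724 with an estimated correlation) on a mean of 0.45 with a median of -0.08 (by number -0.01, -0.02 and 0.02). Adjusted over the list alone, 2 receptors changed, GLR3.6 and GLR3.3, against 1 over all genes; GLR3.5 stood at 0.13 and APY2, an apyrase, at -0.08. The jasmonate call was lost without Col-0 mock 2 (median -0.31), glr3.3glr3.6 mock 2 (-0.12) or glr3.3glr3.6 mock 3 (-0.35), and the epidermis call without Col-0 mock 1 (0.16). The abscisate call was lost without Col-0 mock 1 (-0.13), glr3.3glr3.6 mock 2 (-0.08) or glr3.3glr3.6 mock 3 (-0.17), and the receptors call without glr3.3glr3.6 mock 1 (-0.05). Numbers did not pair all of these libraries. A block on them within genotype, which does not pair the 2 genotypes, ended the receptors call (adjusted p = 0.0908). It called heat shock (median -0.28, adjusted p = 0.0154) and ROS genes (-0.27, adjusted p = 0.000701) lower. With the block across genotypes the receptors call was kept. The abscisate (median -0.10) and receptors calls were lost without the filter on low values, and the receptors call also with library weights (-0.02) or with only these 6 libraries.

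The second genotype comparison asked the same of p2k1p2k2. Libraries labelled p2k1p2k2 mock held 6 genes higher and 0 lower than Col-0 mock (limma; 361 genes at an unadjusted p under 0.05). P2K2 rose by 3.75 ± 0.31 on the log2 scale (22.9 ± 12.9 against 0.641 ± 0.286 FPKM, SD, n = 3, adjusted p = 7.57e-07) and P2K1 by 1.53 (7.64 ± 2.9 against 1.88 ± 0.38 FPKM, adjusted p = 0.0393). QQS (AT3G30720), a gene that affects starch content, rose by 2.33 (54.6 ± 18 against 9.91 ± 3.12 FPKM, adjusted p = 0.00462). ORTHL (AT4G08590), of a family that binds methylated DNA, rose by 1.53 (7.45 ± 1.52 against 1.89 ± 0.224 FPKM, adjusted p = 4.85e-05). AT5G46295 (2.59, 24.3 ± 6.32 against 3.14 ± 0.591 FPKM, adjusted p = 0.0186) and AT3G60940 (1.28, adjusted p = 0.045) rose too. In all 6 the groups did not overlap, which again adds no support. The block within genotype, which does not pair the 2 genotypes, called 10 genes, all 6 among them. It added AT3G61028 (1.67, adjusted p = 0.0113), the brassinosteroid synthesis gene DWF4 (-0.78, 0.0235), EXL3 (-0.71, 0.0235) and XTH19 (-1.56, 0.0362). Across genotypes the block called 9, but not EXL3 or XTH19. Calls fell to 2 without Col-0 mock 1 or Col-0 mock 3, and to 3 without Col-0 mock 2 or p2k1p2k2 mock 2. Without p2k1p2k2 mock 1 there were 5, of which 3 were shared with the 6, and without p2k1p2k2 mock 3 there were 4. P2K2 and ORTHL passed in all 6 refits, and 0 genes passed when only these 6 libraries were fitted. P2K1 did not pass without the filter on low values, nor AT3G60940 at a pseudocount of 0.1.

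For p2k1p2k2 mock, 3 lists differed from Col-0 mock. The jasmonate list was higher (median 0.47, 23 of 24 positive, adjusted p = 8.53e-06, adjusted p = 0.809 with an estimated correlation), with the synthesis genes AOC2 (0.72), AOS (0.50), AOC3 (0.44) and JAR1 (0.38). By number its medians were 1.32, 0.07 and 0.03, and the call was lost without p2k1p2k2 mock 1 (0.04). The list of ROS and high-light acclimation genes was lower (median -0.11, by number -0.01, -0.15 and -0.15, 16 of 25 negative, adjusted p = 0.00458, adjusted p = 0.724 with an estimated correlation). Its ethylene response factors ERF104 (93.3 ± 23.3 against 148 ± 13.4 FPKM) and ERF5 (43.6 ± 8.04 against 65.9 ± 5.39 FPKM) changed when adjusted over the list alone (adjusted p = 0.0371 and 0.0414), against 0 over all genes, beside ERF6 (-0.49) and ZAT10 (-0.29). The ROS call was lost without Col-0 mock 1 (-0.10) or p2k1p2k2 mock 3 (0.00). The receptors list was higher (median 0.08, mean 0.50, by number 0.10, 0.12 and 0.16, 11 of 12 positive, adjusted p = 0.000281, adjusted p = 0.724 with an estimated correlation), with P2K2 and P2K1 changed over all genes and adjusted over the list alone, and GLR3.5 (0.20) and GLR3.6 (0.13) not. Its call held without any 1 library, while the median moved to 0.13 without Col-0 mock 1, 0.01 without Col-0 mock 2, 0.04 without p2k1p2k2 mock 1 and 0.17 without p2k1p2k2 mock 2. The block within genotype also called the lists of calcium and touch genes (adjusted p = 0.0268) and guard cell markers (0.0395) lower.

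In the fit used here, without a block or library weights, no single gene passed the test for either treatment. In the 6 comparisons with mock, limma called 0 of 16577 genes, with 438, 561 and 297 genes at an unadjusted p under 0.05 for eATP in Col-0, glr3.3glr3.6 and p2k1p2k2, and 146, 328 and 285 for L-Glu. Chance alone gives 829. A block on the number within genotype made limma call 8 genes for eATP in glr3.3glr3.6, where numbers did not pair all libraries, 1 for L-Glu there, and 0 in the other 4 comparisons; GA2OX6 was called for both. Library weights called 33 genes for L-Glu and 3 for eATP in glr3.3glr3.6, and MT1A for both in p2k1p2k2, and without the filter on low values AT1G56270 was called for both in Col-0. Every other setting called at most 3 genes in each of the 6. The median SE of a log2 change was 0.18, and in Col-0 the middle 90% of genes lay between -0.32 and 0.29 for eATP and between -0.22 and 0.25 for L-Glu. In simulation, 78.7% of 2-fold and 24.3% of 1.5-fold changes in genes above 5 FPKM were recovered (1 false call). With the block within genotype these were 93.4% and 56.8% (7 false calls). At the level of lists, 22 tests passed at the preset correlation in these 6 comparisons, and they are given genotype by genotype.

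**Figure D3:**
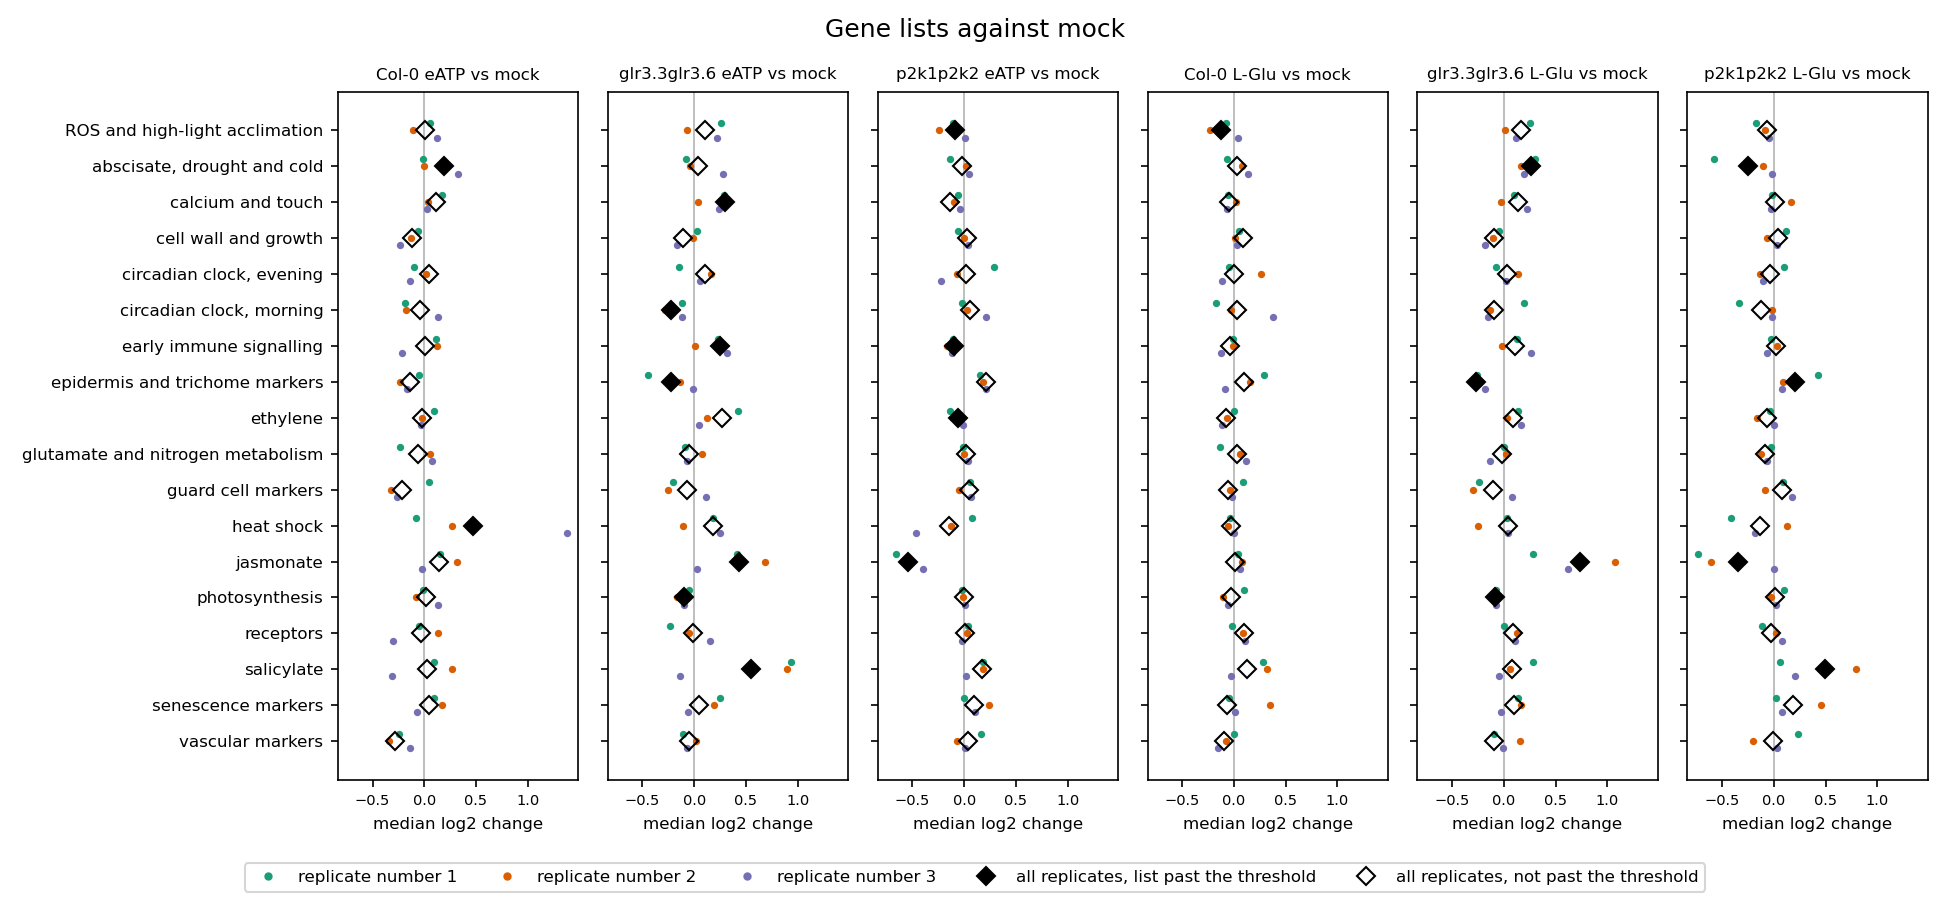
Median log2 change (systemic leaf, treated against mock) of the 18 tested lists in the 6 comparisons with mock, over all replicates (diamonds, filled where the list was called at the preset correlation) and within each replicate number (points). The jasmonate list stands at 0.43 and 0.74 in glr3.3glr3.6 and at -0.54 and -0.35 in p2k1p2k2 for eATP and L-Glu.

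The comparison of eATP with mock in Col-0 asked which transcripts respond in a distant wild-type leaf. Genes of abscisate, drought and cold responses were higher (median 0.19, 14 of 18 positive, adjusted p = 0.00167, adjusted p = 0.724 with an estimated correlation). They included KIN1 (33.3 ± 17.1 against 18.7 ± 2.44 FPKM, SD, n = 3), DREB2A (16 ± 7.9 against 8.87 ± 5.44 FPKM), RD20 (0.62) and NCED3 (0.49), the key enzyme of abscisate synthesis. All 8 heat shock genes were higher (median 0.47, adjusted p = 0.00458, adjusted p = 0.752 with an estimated correlation), with HSP101 at 4.27 ± 0.796 against 2.99 ± 0.584 FPKM, HSP90.1 (0.65), MBF1C (0.53) and HSP70 (0.52). No member of these lists passed alone, over all genes or adjusted over the list alone. By number the medians were -0.01, -0.00 and 0.33 for abscisate and -0.08, 0.27 and 1.38 for heat shock. The heat shock call was lost without Col-0 eATP 3 (median 0.03) or Col-0 mock 2 (0.38). Library weights ended it too (0.13). Col-0 eATP 3 stood apart from the other 26 libraries, with the highest second principal component (35.8, next 24), summed FPKM (822758, next 786962) and mean of the heat shock list (0.99 on the centred log2 scale, next 0.67). The abscisate call was kept without any 1 library, though its median fell to 0.07 without Col-0 eATP 3. Vascular markers were not called (median -0.28, by number -0.24, -0.34 and -0.14, 8 of 9 negative, adjusted p = 0.051, adjusted p = 0.724 with an estimated correlation). A block on the number, which did not pair all of these libraries, called them lower (adjusted p = 0.00415) and calcium and touch (0.0344) and jasmonate genes (0.00676) higher. The genes with the smallest p, none passing (adjusted p = 1), were AT1G57700 (2.55 ± 0.346 against 3.98 ± 0.346 FPKM), AT1G74385 (0.47 ± 0.812 against 60.8 ± 23.7 FPKM), AT4G35540 (0.44), AT3G12940 (-0.50) and AT1G71980 (-0.40).

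In the libraries labelled glr3.3glr3.6, 7 lists differed after eATP, with 4 defence and signalling lists higher and 3 lists lower than mock. Salicylate genes were higher (median 0.55, mean 0.93, by number 0.94, 0.90 and -0.14, 12 of 13 positive, adjusted p = 1.16e-05, adjusted p = 0.752 with an estimated correlation), with the synthesis genes ICS1 (34.6 ± 22.6 against 14.5 ± 7.99 FPKM) and PBS3 (11.7 ± 10.3 against 2.48 ± 2.99 FPKM), EDS5 (0.68), and the immune regulator EDS1 (59.7 ± 18.1 against 39.9 ± 1.49 FPKM). Jasmonate genes were higher (median 0.43, by number 0.41, 0.68 and 0.03, 23 of 24 positive, adjusted p = 0.000525, adjusted p = 0.883 with an estimated correlation), with LOX3 (33.4 ± 10.2 against 16.8 ± 4.77 FPKM), AOC3 (0.66), JAZ1 (0.54) and the jasmonate-degrading CYP94B3 (1.38). Calcium and touch genes were higher (median 0.30, by number 0.29, 0.04 and 0.24, 14 of 17 positive, adjusted p = 0.00339, adjusted p = 0.809 with an estimated correlation), with the calmodulin-like CML41 (1.66) and CML37 (0.86), the calcium pump ACA13 (0.50) and the annexin ANNAT1 (0.34). Early immune genes were higher (median 0.25, by number 0.23, 0.01 and 0.32, 18 of 23 positive, adjusted p = 0.0198, adjusted p = 0.927 with an estimated correlation), with NHL10 (1.51), PER4 (0.71), WRKY53 (0.55) and MKK4 (0.29).

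In the same libraries, photosynthesis genes were lower after eATP by a small amount (median -0.10, by number -0.05, -0.17 and -0.10, 20 of 21 negative, adjusted p = 0.000104, adjusted p = 0.838 with an estimated correlation), such as RBCS2B (1680 ± 122 against 1930 ± 107 FPKM), LHCB2.1, LHCA4 and LHCA3. Epidermis and trichome markers were lower (median -0.22, by number -0.45, -0.14 and -0.01, 6 of 7 negative, adjusted p = 0.0089, adjusted p = 0.724 with an estimated correlation), with ATML1 (-0.26), LTP1 (-0.23) and PDF2 (-0.22). FDH, an enzyme of epidermal lipid synthesis, stood at 182 ± 23.3 against 243 ± 6.92 FPKM and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0338), against 0 over all genes. Morning clock genes were lower (median -0.22, by number -0.12, -0.28 and -0.12, 7 of 9 negative, adjusted p = 0.0337, adjusted p = 0.865 with an estimated correlation), with PRR9 (-0.32), RVE1 (-0.25), LNK2 (-0.23) and PRR7 (-0.22). The 7 calls of this comparison depended on single libraries. Without glr3.3glr3.6 eATP 1 they were lost for salicylate (median 0.41), jasmonate (0.20), calcium (0.09), early immune (0.09) and epidermis (-0.04), and without glr3.3glr3.6 eATP 2 for the morning clock (-0.07). Without glr3.3glr3.6 mock 2 they were lost for jasmonate (0.21), photosynthesis (-0.06) and epidermis (-0.21), without mock 3 for calcium (0.15), early immune (0.06) and morning clock (-0.11), and without mock 1 for the morning clock (-0.23). Quantile normalization ended the calls of photosynthesis (-0.01) and morning clock (-0.27), median-of-ratios scaling those of morning clock (-0.24) and early immune (0.23), library weights those of calcium (0.14), early immune (0.10) and morning clock (-0.11), and a minimum of 5 FPKM that of morning clock (-0.22). Numbers did not pair all of these libraries, and a block on them also called ethylene genes higher (adjusted p = 0.0179). The smallest p belonged to AT5G57010 (7.46 ± 0.138 against 3.85 ± 1.45 FPKM), AT1G09907 (-1.46), AT5G57080 (0.99), AT4G26120 (0.80) and MIR830 (9.35 ± 9.17 FPKM, listed at 0 in mock), none of which passed (smallest adjusted p = 0.733).

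After eATP, 4 lists were lower than after mock in the libraries labelled p2k1p2k2. All 24 jasmonate genes were lower (median -0.54, by number -0.66, -0.54 and -0.40, adjusted p = 9.14e-15, adjusted p = 0.724 with an estimated correlation), among them AOS (145 ± 40.5 against 224 ± 95.6 FPKM), AOC3 (59.6 ± 15.7 against 90.9 ± 20.5 FPKM), JAZ7 (-1.38) and CYP94C1 (-0.88). Early immune genes were slightly lower (median -0.10, by number -0.11, -0.17 and -0.12, 19 of 23 negative, adjusted p = 0.000612, adjusted p = 0.809 with an estimated correlation), with the kinases MKK4 (-0.29), MKK5 (-0.19) and MKK9 (-0.17) and the ubiquitin ligase PUB22 (-0.23). ROS and high-light genes were lower (median -0.09, by number -0.11, -0.24 and 0.01, 18 of 25 negative, adjusted p = 0.00834, adjusted p = 0.724 with an estimated correlation), with the peroxidase APX1 (381 ± 38.2 against 468 ± 58.5 FPKM), ERF109 (-1.08), ZAT12 (-0.36) and ZAT10 (-0.21). Ethylene genes were lower (median -0.06, by number -0.14, -0.06 and -0.01, 11 of 15 negative, adjusted p = 0.00834, adjusted p = 0.724 with an estimated correlation), with ERF4 and ERF11 (both -0.45), ACS6 (-0.22) and ERF1A (-0.19). No member passed alone. Blocking on the number added calls of epidermis markers, higher (adjusted p = 0.00456), and heat shock genes, lower (0.0414). The jasmonate call held without any 1 library, but its median moved to -0.14 without p2k1p2k2 mock 1, -0.29 without eATP 3, -0.87 without mock 3 and -0.88 without eATP 1. The others were lost without p2k1p2k2 mock 1 (medians -0.03 for early immune, -0.06 for ROS and -0.03 for ethylene) and without p2k1p2k2 eATP 2 (-0.01, 0.00 and -0.07), and ethylene also without eATP 3 (-0.06). Ethylene and ROS were also lost under quantile normalization (-0.10 and -0.12) and without the filter (-0.06 and -0.08). Not passing (adjusted p = 1), the smallest p were those of MT1A, AT1G09907 (1.28), AT5G03050 (0.67), CHY1 (0.30) and the clock-related ELF4-L2 (0.50). MT1A, a metallothionein, was at 110 and 39.1 FPKM in p2k1p2k2 mock 2 and 3, and at most 0.111 FPKM in every other library.

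The comparison of L-Glu with mock in Col-0 asked the same of glutamate. ROS and high-light acclimation genes were the 1 list that differed, and they were lower (median -0.13, by number -0.08, -0.23 and 0.04, 18 of 25 negative, adjusted p = 0.00174, adjusted p = 0.724 with an estimated correlation). The ethylene response factors ERF104 (108 ± 24.2 against 148 ± 13.4 FPKM), ERF5 (48.9 ± 14.2 against 65.9 ± 5.39 FPKM) and ERF6 (-0.29) had the smallest p, while the superoxide dismutase FSD1 stood at 0.19. No member passed alone. Ethylene genes (adjusted p = 0.00987) and photosynthesis genes (0.023) were called lower too with the number as a block. The ROS call was lost without Col-0 mock 1 (median -0.04) or Col-0 L-Glu 2 (-0.05). No gene passed (smallest adjusted p = 1), the first being AT2G08330 and AT1G06457 (25.5 ± 22.2 and 28.6 ± 26.2 FPKM, at or near 0 in mock), AT4G32272 (5.62 ± 0.521 against 3.98 ± 0.0655 FPKM), the translation factor eIF4E3 (0.70) and AT2G27340 (0.60).

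Jasmonate genes were higher after L-Glu in the libraries labelled glr3.3glr3.6 (median 0.74, by number 0.28, 1.07 and 0.62, 22 of 24 positive, adjusted p = 4.09e-11, adjusted p = 0.724 with an estimated correlation). CYP94B3 stood at 14.1 ± 9.81 against 1.31 ± 1.87 FPKM and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0227), against 0 over all genes. AOC2 (184 ± 13.9 against 107 ± 47.3 FPKM), AOC3 (80.3 ± 11.2 against 47.8 ± 20.4 FPKM) and AOS (0.56), which make jasmonate precursors, stood higher as well. Genes of abscisate, drought and cold were higher (median 0.26, by number 0.30, 0.17 and 0.19, 16 of 18 positive, adjusted p = 0.00947, adjusted p = 0.724 with an estimated correlation), with DREB2A (0.70), COR15B (0.38), COR15A (0.34) and ABI2 (0.31). All 7 epidermis and trichome markers were lower (median -0.27, by number -0.26, -0.25 and -0.18, adjusted p = 0.00834, adjusted p = 0.724 with an estimated correlation), with FDH at 198 ± 5.67 against 243 ± 6.92 FPKM, PDF2 (-0.27), LTP1 (-0.19) and ATML1 (-0.16). Photosynthesis genes were lower (median -0.09, by number -0.08, -0.11 and -0.08, 20 of 21 negative, adjusted p = 0.000612, adjusted p = 0.865 with an estimated correlation), though not under quantile normalization, where the median was -0.01 and the test pointed up. RBCS2B (-0.25), LHCB2.1 (-0.16), LHCA1 and LHCA3 (both -0.12) had the smallest p.

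The jasmonate call for L-Glu in glr3.3glr3.6 held without any 1 library, with a median of 0.47 without glr3.3glr3.6 mock 2. Without glr3.3glr3.6 mock 2 the calls were lost for abscisate (median 0.16), epidermis (-0.20) and photosynthesis (-0.04), without L-Glu 1 for abscisate (0.15) and epidermis (-0.15), without L-Glu 3 for photosynthesis (-0.04), and without mock 1 for epidermis (-0.31). Calcium and touch (adjusted p = 0.0386), early immune (0.0158) and ROS genes (0.0194) were called higher too with the number as a block. That block also called 1 gene, GA2OX6, a gibberellin-inactivating enzyme (0.71 ± 0.10, 86.6 ± 16.2 against 52.4 ± 10.2 FPKM, adjusted p = 0.0398). Without the block it did not pass, nor did AT1G22830 (0.94), AT5G57080 (0.99), the lipid kinase DGK2 (22 ± 8.92 against 8.69 ± 2.05 FPKM) or AT2G35736 (1.72), with a smallest adjusted p of 0.706.

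Jasmonate genes were lower after L-Glu in the libraries labelled p2k1p2k2 (median -0.35, by number -0.73, -0.61 and -0.00, 21 of 24 negative, adjusted p = 7.18e-07, adjusted p = 0.752 with an estimated correlation), with OPR3 (142 ± 60.2 against 251 ± 171 FPKM), LOX3 (-0.71), AOS (-0.62) and JAR1 (-0.44). All 13 salicylate genes were higher (median 0.49, by number 0.06, 0.79 and 0.20, adjusted p = 0.000699, adjusted p = 0.838 with an estimated correlation), with WRKY70 (105 ± 15.2 against 72.3 ± 17.2 FPKM), SARD1 (0.73), PAD4 (0.54) and EDS1 (0.30). Abscisate, drought and cold genes were lower (median -0.25, by number -0.58, -0.10 and -0.02, 14 of 18 negative, adjusted p = 0.00155, adjusted p = 0.724 with an estimated correlation), with RD29A (-0.83), COR15A (-0.48), NCED3 (1.85 ± 0.0667 against 2.87 ± 0.193 FPKM) and COR47 (-0.39). All 7 epidermis markers were higher (median 0.20, by number 0.43, 0.09 and 0.08, adjusted p = 0.0243, adjusted p = 0.752 with an estimated correlation), with CER6 (0.27), ATML1 (0.20), FDH and PDF2 (both 0.18). No member passed alone. With the number as a block, morning clock (adjusted p = 0.0313) and ROS genes (0.0108) were called lower too. Without p2k1p2k2 mock 1 the calls were lost for jasmonate (median -0.06), abscisate (0.04) and epidermis (0.04), without mock 2 or mock 3 for salicylate (0.27 and 0.29), without L-Glu 1 for salicylate (0.20), without L-Glu 2 for abscisate (-0.10) and without L-Glu 3 for epidermis (0.13). The epidermis call was also lost without the filter (0.18), with library weights (0.11) and with only these 6 libraries (0.20). The smallest p, none passing (smallest adjusted p = 0.912), were those of AT3G15420 (-0.76), MT1A (-4.04), AT4G08795 (-2.08), AT1G09907 (2.17 ± 1.06 against 0.294 ± 0.509 FPKM) and AT3G17717 (-1.18).

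The direct comparison of eATP with L-Glu asked where the stimuli differ. In Col-0, 6 lists were higher after eATP than after L-Glu. Heat shock genes (median 0.43, by number 0.01, 0.27 and 1.39, 8 of 8 positive, adjusted p = 0.00458, adjusted p = 0.752 with an estimated correlation) included HSP90.1 (0.57), MBF1C (0.56), HSP70 (0.55) and HSFB2A (0.14). Abscisate, drought and cold genes (median 0.17, by number 0.09, 0.16 and 0.27, 15 of 18 positive, adjusted p = 0.00514, adjusted p = 0.724 with an estimated correlation) included DREB2A (0.75), KIN1 (0.66), RD20 (0.48) and COR15A (0.34). ROS and high-light genes (median 0.12, by number 0.13, 0.16 and 0.08, 18 of 25 positive, adjusted p = 0.00525, adjusted p = 0.724 with an estimated correlation) included APX1 (454 ± 104 against 380 ± 54.4 FPKM), ERF5 (0.24), CSD1 (0.22) and ERF6 (0.17). Calcium and touch genes (median 0.20, by number 0.30, 0.11 and 0.08, 13 of 17 positive, adjusted p = 0.0177, adjusted p = 0.883 with an estimated correlation) included CML42 (0.43), CML24 (0.33) and CML38 (0.29), with the vacuolar channel TPC1 at -0.26. Jasmonate genes (median 0.15, by number 0.22, 0.25 and 0.05, 20 of 24 positive, adjusted p = 0.0337, adjusted p = 0.961 with an estimated correlation) included AOC1 (0.35), AOC2 (0.31) and AOC3 (0.28), with LOX6 at -0.28. Photosynthesis genes (median 0.04, -0.02 under quantile normalization, by number -0.09, 0.03 and 0.18, 16 of 21 positive, adjusted p = 0.0217, adjusted p = 0.951 with an estimated correlation) included LHCB6 (0.14), LHCB3 and LHCB5 (both 0.11) and LHCB1.3 (0.10).

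For single genes, limma called 0 between eATP and L-Glu in Col-0 (999 at an unadjusted p under 0.05, smallest adjusted p = 0.825). The first were AT2G08330 and AT1G06457, at or near 0 after eATP, and AT2G18840 (-0.43), the chloroplast RNA factor HCF107 (-0.37) and the RNA-binding PUM4 (-0.47). With the number as a block 1 gene was called, the subtilase SLP2 (-0.53 ± 0.07, adjusted p = 0.0172), and so were ethylene genes (higher, 0.0157) and epidermis markers (lower, 0.0157). Adjusted over the list alone, 1 member of the cell wall and growth list passed, the expansin EXPA8 (2.8 ± 0.639 against 5.53 ± 0.923 FPKM, adjusted p = 0.0255). Without Col-0 eATP 3, list calls were lost for heat shock (median 0.07), abscisate (0.02) and photosynthesis (-0.00), without eATP 1 for calcium (-0.04), jasmonate (0.08) and ROS (-0.02), and without eATP 2 for jasmonate (0.02) and photosynthesis (0.02). Without Col-0 L-Glu 2 they were lost for abscisate (0.16), calcium (0.11) and ROS (0.06), and without L-Glu 3 for calcium (0.10), jasmonate (0.03) and photosynthesis (0.01). Quantile normalization ended all calls but heat shock (abscisate 0.19, calcium and jasmonate 0.17, ROS 0.13), and median-of-ratios scaling ended calcium (0.27) and jasmonate (0.23). Calcium (0.21), jasmonate (0.18) and photosynthesis (0.04) were lost without the filter, jasmonate at a minimum of 5 FPKM (0.16), and photosynthesis with only these libraries (0.04).

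In the libraries labelled glr3.3glr3.6, all 13 salicylate genes were higher after eATP than after L-Glu (median 0.45, by number 0.66, 0.83 and -0.13, adjusted p = 3.82e-06, adjusted p = 0.724 with an estimated correlation), with PBS3 (11.7 ± 10.3 against 1.99 ± 0.598 FPKM), ICS1 (1.08), EDS1 (0.51) and CBP60G (0.45). Jasmonate genes were lower (median -0.14, by number 0.17, -0.05 and -0.42, 20 of 24 negative, adjusted p = 0.0262, adjusted p = 0.961 with an estimated correlation), with CYP94B3 (-1.35) and the storage proteins VSP2 (-0.77) and VSP1 (-0.61), and JAR1 at 0.20. The salicylate call was lost without glr3.3glr3.6 eATP 1 (0.29), and the jasmonate call without eATP 2 (-0.12), eATP 3 (0.09) or L-Glu 1 (-0.05). The jasmonate call was also lost under quantile normalization (-0.17), median-of-ratios scaling (-0.15), no filter (-0.14) and a minimum of 5 FPKM (-0.12). With the number as a block, abscisate (adjusted p = 0.0128), morning clock (0.0128) and receptors (0.045) were called lower and calcium and touch (0.0125) higher. Limma called 0 genes (276 at an unadjusted p under 0.05, smallest adjusted p = 0.416), the first being AT1G09907 (-1.54), AT1G22830 (-0.89), AT4G04200 (8.07 ± 0.553 against 4.63 ± 0.612 FPKM), MIR830 (listed at 0 after L-Glu) and AT3G01505 (57.8 ± 17.2 against 0.00297 ± 0.00224 FPKM).

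In the libraries labelled p2k1p2k2, 3 lists were lower after eATP than after L-Glu. Early immune genes (median -0.12, by number -0.04, -0.24 and -0.04, 19 of 23 negative, adjusted p = 0.00172, adjusted p = 0.838 with an estimated correlation) included PER4 (-0.36), WRKY29 (-0.27), the flagellin receptor FLS2 (-0.27) and MKK5 (-0.13). Salicylate genes (median -0.19, by number 0.21, -0.61 and -0.23, 11 of 13 negative, adjusted p = 0.00538, adjusted p = 0.927 with an estimated correlation) included SARD1 (-0.42), WRKY70 (-0.38), EDS5 (-0.36) and CBP60G (-0.19). Jasmonate genes (median -0.08, by number 0.14, -0.00 and -0.42, 18 of 24 negative, adjusted p = 0.0315, adjusted p = 0.961 with an estimated correlation) included VSP2 (-0.92), VSP1 (-0.49), AOC3 (-0.28) and LOX6 (-0.13). With the number as a block, abscisate (adjusted p = 0.0145) and morning clock genes (0.00604) were called higher and calcium and touch genes (0.0221) lower. All 3 calls were lost without p2k1p2k2 eATP 2 (medians -0.00 for early immune, -0.11 for salicylate and 0.08 for jasmonate) or L-Glu 1 (0.00, -0.10 and 0.11), and salicylate and jasmonate also without eATP 3 (-0.03 and 0.11). Jasmonate was lost as well under quantile normalization (-0.10), median-of-ratios scaling (-0.11), no filter (-0.07), a minimum of 5 FPKM or only these libraries (both -0.08), and salicylate without the filter (-0.19). Limma called 0 genes (270 at an unadjusted p under 0.05, smallest adjusted p = 1), the first being AT4G08795 (2.15), AT3G26395 (10.2 ± 2.05 against 5.04 ± 1.78 FPKM), AT5G19595 (listed at 0 after eATP), AT3G19508 (0.76) and ECIP1 (0.43).

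Whether both stimuli move the same genes was asked within each genotype. As 0 genes were called, 0 were shared (1 test per genotype by limma). Across the 16577 genes, eATP and L-Glu changes correlated at 0.45 in Col-0, 0.60 in glr3.3glr3.6 and 0.49 in p2k1p2k2, where 2 unchanged groups set against the same 3 mocks gave 0.50 in simulation. Genes are not independent replicates. The covariance exceeded the simulated one by 0.0138 in glr3.3glr3.6, and differed by -0.0023 in Col-0 and -0.0013 in p2k1p2k2.

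The last comparisons asked whether the mutants respond to the stimuli differently from Col-0, as the difference of log2 changes. In glr3.3glr3.6, the eATP response of all 13 salicylate genes was higher than in Col-0 (median 0.65, by number 0.71, 0.83 and 0.26, adjusted p = 0.00167, adjusted p = 0.883 with an estimated correlation), with PBS3 (1.75), EDS5 (0.89), EDS1 (0.62) and CBP60G (0.58). That of photosynthesis genes was lower (median -0.15, by number -0.05, -0.05 and -0.22, 17 of 21 negative, adjusted p = 4.39e-05, adjusted p = 0.809 with an estimated correlation), with LHCB2.1 (-0.27), LHCB3 (-0.19), LHCA4 and RCA (both -0.17). The photosynthesis call held without any 1 library, with a median of -0.05 without Col-0 mock 1 and -0.09 without Col-0 eATP 3 or glr3.3glr3.6 mock 2. The salicylate call was lost without Col-0 mock 1 (0.34), Col-0 eATP 3 (0.32) or glr3.3glr3.6 eATP 1 (0.28). Quantile normalization ended the photosynthesis call (-0.00), and library weights the salicylate call (0.41). A block on the number, which did not pair all of these libraries, also called jasmonate (adjusted p = 0.0268) and early immune genes (0.0409) higher and abscisate (0.0253) and heat shock genes (0.023) lower. Limma called 0 genes (294 at an unadjusted p under 0.05, smallest adjusted p = 1), the first being AT5G57080 (1.41), the pyrimidine-degrading PYD1 (0.70), AT1G57700 (0.60), AT5G57010 (0.93) and AT2G26515 (-1.45).

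In p2k1p2k2, the eATP response of 23 of 24 jasmonate genes was lower than in Col-0 (median -0.75, by number -0.93, -0.91 and -0.33, adjusted p = 1.97e-10, adjusted p = 0.724 with an estimated correlation), with CYP94C1 (-1.23), AOC3 (-0.92), AOS (-0.59) and JAZ6 (-0.50). Heat shock genes responded lower (median -0.62, by number -0.06, -0.35 and -1.59, 7 of 8 negative, adjusted p = 0.00186, adjusted p = 0.724 with an estimated correlation), with HSFA2 (-1.13), HSP70 (-0.91), HSP101 (-0.71) and HSFB2A (-0.27). So did abscisate, drought and cold genes (median -0.21, by number -0.19, 0.01 and -0.36, 13 of 18 negative, adjusted p = 0.00167, adjusted p = 0.724 with an estimated correlation), with KIN1 (-1.06), RD20 (-0.84), NCED3 (-0.81) and COR47 (-0.34). Lower responses were also called for calcium and touch (median -0.25, by number -0.24, -0.21 and -0.12, adjusted p = 0.0337, adjusted p = 0.927 with an estimated correlation), with CML23 (-0.58), CML24 (-0.45), CML12 (-0.25) and TPC1 (0.25), and for early immune genes (median -0.13, by number -0.13, -0.26 and 0.10, adjusted p = 0.0126, adjusted p = 0.927 with an estimated correlation), with WRKY18 (-0.63), PUB22 (-0.35), MKK5 (-0.13) and MPK6 (0.17). ROS and high-light genes were called lower as well (median -0.14, by number 0.04, -0.14 and -0.03, adjusted p = 0.0411, adjusted p = 0.78 with an estimated correlation), with ERF109 (-1.55), AOX1A (-0.56), APX1 (-0.41) and ERF104 (0.56). The ethylene list was called lower on a mean of -0.18 with a median of 0.01 (by number -0.19, -0.08 and -0.16, adjusted p = 0.0315, adjusted p = 0.724 with an estimated correlation), with ERF11 (-0.76), ERF4 (-0.64), ERF2 (-0.26) and EBF2 (0.31).

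Of those 7 calls for p2k1p2k2, jasmonate and abscisate held without any 1 library, with smaller medians in some refits. The jasmonate median was -0.27 without p2k1p2k2 mock 1 and -0.47 without p2k1p2k2 eATP 3, and the abscisate median -0.01 without p2k1p2k2 mock 1, -0.09 without Col-0 eATP 3 and -0.12 without p2k1p2k2 eATP 2. Heat shock was lost without Col-0 eATP 3 (median -0.32) or p2k1p2k2 eATP 2 (-0.30). Calcium was lost without Col-0 mock 2 (-0.06), Col-0 mock 3 (-0.15), Col-0 eATP 1 (-0.07), p2k1p2k2 mock 1 (-0.03), p2k1p2k2 eATP 2 (-0.12) or eATP 3 (-0.02). Early immune was lost without Col-0 mock 2 (-0.02), Col-0 eATP 1 (-0.01), p2k1p2k2 mock 1 (-0.02) or eATP 2 (-0.02). Ethylene was lost without Col-0 mock 1 (-0.19), mock 2 (-0.07), eATP 1 (0.02) or eATP 2 (-0.09), or p2k1p2k2 mock 1 (0.05), eATP 2 (0.01) or eATP 3 (-0.02). ROS was lost without Col-0 mock 2 (-0.18), mock 3 (-0.01) or eATP 1 (0.07), or p2k1p2k2 mock 1 (-0.06), mock 2 (-0.16), eATP 2 (-0.06) or eATP 3 (-0.15). Calcium, early immune, ethylene and ROS were also lost under quantile normalization (-0.18, -0.09, -0.10 and -0.12) and without the filter (-0.22, -0.12, -0.03 and -0.14). Under median-of-ratios scaling calcium (-0.34), ethylene (-0.07) and ROS (-0.22) were lost, and at a minimum of 5 FPKM calcium (-0.25). Epidermis markers were called higher with a block on the number (adjusted p = 0.0022), which did not pair all of these libraries. Limma called 0 genes (477 at an unadjusted p under 0.05, smallest adjusted p = 1), the first being AT1G71980 (0.61), AT3G12940 (0.73), AT4G35540 (-0.59), the growth regulator TCP15 (0.74) and AT3G29644 (1.43).

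In glr3.3glr3.6, the L-Glu response of 21 of 24 jasmonate genes was higher than in Col-0 (median 0.71, by number 0.22, 1.16 and 0.55, adjusted p = 4.29e-08, adjusted p = 0.724 with an estimated correlation), with CYP94B3 (2.43), AOC2 (0.97), AOC3 (0.78) and AOS (0.70). Higher responses were also called for ethylene genes (median 0.24, by number 0.21, 0.05 and 0.37, 11 of 15 positive, adjusted p = 0.0126, adjusted p = 0.724 with an estimated correlation), with ERF1 (0.60), ERF11 (0.41), ERF4 (0.34) and EBF1 (0.24), and for ROS genes (median 0.22, by number 0.33, 0.12 and 0.24, 21 of 25 positive, adjusted p = 0.00458, adjusted p = 0.724 with an estimated correlation), with OXI1 (0.88), UPOX (0.68), APX1 (0.51) and MYB30 (-0.26). Early immune genes were called higher (median 0.12, by number 0.09, -0.08 and 0.39, 20 of 23 positive, adjusted p = 0.0332, adjusted p = 0.927 with an estimated correlation), with WRKY29 (0.41), MKK4 (0.29), BAK1 (0.26) and MPK6 (-0.16). All 7 epidermis markers responded lower (median -0.35, by number -0.68, -0.24 and -0.13, adjusted p = 0.00926, adjusted p = 0.724 with an estimated correlation), with FDH (-0.44), PDF2 (-0.37), LTP1 (-0.33) and ATML1 (-0.27). The jasmonate call held without any 1 library. Epidermis was lost without Col-0 mock 1 (-0.18), Col-0 L-Glu 2 (-0.19) or glr3.3glr3.6 mock 2 (-0.29), and ethylene without glr3.3glr3.6 mock 3 (0.23) or L-Glu 1 (0.13). ROS was lost without Col-0 mock 1 (0.11), Col-0 L-Glu 2 (0.14), glr3.3glr3.6 mock 3 (0.19) or L-Glu 1 (0.11). Early immune was lost without Col-0 mock 1 (0.05), mock 3 (0.12), L-Glu 2 (0.07) or L-Glu 3 (0.08), or glr3.3glr3.6 mock 3 (0.04) or L-Glu 1 (0.00). Early immune was lost also under quantile normalization (0.08), median-of-ratios scaling (0.15) and no filter (0.11), and ethylene under quantile normalization and no filter (both 0.23). Numbers did not pair all of these libraries, and blocking on them called calcium (adjusted p = 0.00604) and abscisate genes (0.0187) higher too. Limma called 0 genes (222 at an unadjusted p under 0.05, smallest adjusted p = 1), the first being AT3G01505 (-7.70), AT1G64561 (-1.45), AT2G35420 (1.16), AT2G33510 (-0.84) and ATCG01180 (1.12).

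In p2k1p2k2, the L-Glu response of 20 of 24 jasmonate genes was lower than in Col-0 (median -0.45, by number -0.71, -0.57 and 0.02, adjusted p = 0.00155, adjusted p = 0.927 with an estimated correlation), with LOX3 (-0.82), JAZ2 (-0.68), AOS (-0.48) and JAR1 (-0.44). That of abscisate, drought and cold genes was lower too (median -0.28, by number -0.48, -0.10 and -0.16, 14 of 18 negative, adjusted p = 0.0155, adjusted p = 0.724 with an estimated correlation), with RD29A (-0.92), NCED3 (-0.81), COR47 (-0.39) and the phosphatase ABI1 (-0.25). With the number as a block, salicylate genes were called higher (adjusted p = 0.0253). The jasmonate call was lost without p2k1p2k2 mock 1 (-0.08, the test pointing up), L-Glu 2 (-0.27) or L-Glu 3 (-0.37), and the abscisate call without Col-0 mock 2 (-0.30), Col-0 mock 3 (-0.25), Col-0 L-Glu 1 (-0.26), p2k1p2k2 mock 1 (-0.08) or L-Glu 2 (-0.19), and without the filter on low values (-0.26). Limma called 0 genes (176 at an unadjusted p under 0.05, smallest adjusted p = 1), the first being AT4G08795 (-2.84), AT3G19508 (-1.22), eIF4E3 (-0.86), EXPA8 (-1.05, 1 member of its list past the threshold adjusted over the list alone, adjusted p = 0.0413) and AT1G09907 (1.53).

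Several lists were not called in any of the 15 comparisons without a block on the number. Medians ran from -0.20 to 0.15 for cell wall and growth (smallest adjusted p = 0.115), from -0.09 to 0.10 for the evening clock (0.166) and from -0.09 to 0.10 for glutamate and nitrogen metabolism (0.241). Among cell type markers they ran from -0.22 to 0.28 for guard cells (0.189), from -0.28 to 0.27 for vasculature (0.051) and from -0.07 to 0.19 for senescence (0.358). Of these 6 lists, the block called guard cell markers in p2k1p2k2 mock and vascular markers for eATP in Col-0, as given above. Flower, root, and shoot apex markers had 1, 2 and 1 members above the minimum level and were not tested. Over all lists 56 of 270 tests passed at the preset correlation and 0 with an estimated one (17 at an unadjusted p under 0.05), so each list call rests on the preset correlation between genes. Outside the receptors, 6 members changed when adjusted over the list alone and 0 over all genes.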

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

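The tests of explanations and of other splits in this part were chosen after the result was seen; the differences between responses were planned. A total of 16 list results stand here because the response of a mutant differed from that of Col-0 in a test of the difference itself, with camera at its preset correlation. With an estimated correlation none of the 16 passed (adjusted p from 0.724 to 0.927), and 12 lost their call without 1 of the libraries, as given library by library in the results. Values are the median difference of log2 changes, mutant minus Col-0.

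For eATP in glr3.3glr3.6, the photosynthesis list stood at -0.15 and the salicylate list at 0.65. With the libraries of the 2 genotypes regrouped within treatment, 82 of 100 splits called as many lists (2 real, 9 at most in the others, adjusted within the comparison). Those splits ignored the replicate number. In splits that exchanged genotypes only within treatment and number, 24 of 32 called as many (8 at most), so chance is not excluded. For eATP in p2k1p2k2, the lists stood at -0.21 for abscisate, drought and cold, -0.25 for calcium and touch, -0.13 for early immune signalling, 0.01 for ethylene (mean -0.18), -0.62 for heat shock, -0.75 for jasmonate and -0.14 for ROS and high-light acclimation. Here 24 of 100 splits called as many lists (8 real, 13 at most), and 2 of 32 with the number kept (10 at most), a share just above 0.05, so chance is not excluded. For genes, a real count of 0 makes all 100 splits as large whatever the data, so that count tests nothing in any of the 4 responses. The splits called at most 76 genes for eATP in glr3.3glr3.6 and 50 in p2k1p2k2, which points to a structure of the libraries other than genotype, and at most 10 and 1 for L-Glu.

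For L-Glu in glr3.3glr3.6, the lists stood at 0.12 for early immune signalling, -0.35 for epidermis and trichome markers, 0.24 for ethylene, 0.71 for jasmonate and 0.22 for ROS and high-light acclimation. As many lists were called in 24 of 100 splits (7 real, 10 at most), and in 2 of 32 with the number kept (8 at most), so chance is not excluded here either. For L-Glu in p2k1p2k2, the lists stood at -0.28 for abscisate, drought and cold and -0.45 for jasmonate. As many lists were called in 87 of 100 splits (2 real, 10 at most). Replicate numbers pair these libraries, and with the number kept 22 of 32 splits called as many lists (6 at most), so chance is not excluded.

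The jasmonate list was higher than mock in glr3.3glr3.6 (0.43 for eATP, 0.74 for L-Glu) and lower in p2k1p2k2 (-0.54 and -0.35). Of 24 refits that each left out 1 library, 3 lost one of these calls (eATP in glr3.3glr3.6 without mock 2 or eATP 1, L-Glu in p2k1p2k2 without mock 1) and 0 turned the direction. The other 2 calls were kept, but for eATP in p2k1p2k2 the median fell to -0.14 without mock 1 (adjusted p = 0.024), and for L-Glu in glr3.3glr3.6 it fell to 0.47 without mock 2, so 1 odd library stays open as part of the pattern. Mocks at different levels could give the opposite changes: the list's median, p2k1p2k2 minus glr3.3glr3.6, was 0.75 between mocks and -0.19 between treated libraries. The mock gap rests on 2 libraries, p2k1p2k2 mock 1, the highest of the 27, and glr3.3glr3.6 mock 2, the lowest (-0.77 from their mean), and was 0.06 without both. In numbers 1, 2 and 3 it was 1.09, 1.08 and 0.12, against 0.13, -0.56 and -0.31 between treated libraries, so the treated gap was the larger one in number 3. These values do not decide between different mock plants, by genotype or by the handling of single pools, and a biological difference in the response of each genotype, since both are read against the same 3 mocks.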

How the results depend on the processing

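The block across genotypes and the averaged effects were chosen after the data were seen; the other alternatives were planned. The counts of genes called in the 15 comparisons stayed within 1.5 times under a pseudocount of 0.1, quantile normalization and median-of-ratios scaling. They moved as follows, and the cause was not tested. Without a filter, eATP and L-Glu against mock in Col-0 each called 1 gene instead of 0, and 1 was shared between them. With a mean of at least 5 FPKM, p2k1p2k2 mock called 3 instead of 6, with fewer genes tested. With the replicate block within genotype, calls were 8 for eATP and 1 for L-Glu in glr3.3glr3.6 (1 shared), 1 for eATP against L-Glu in Col-0, 13 for glr3.3glr3.6 mock and 10 for p2k1p2k2 mock. With the block across genotypes they were 1 for eATP in Col-0 and 3 for eATP in glr3.3glr3.6. With library weights they were 3 for eATP and 33 for L-Glu in glr3.3glr3.6 (1 shared), 1 for eATP and 1 for L-Glu in p2k1p2k2 (1 shared), and 1 for eATP against L-Glu in glr3.3glr3.6. With only the libraries compared they were 1 for L-Glu in Col-0, 1 for L-Glu in p2k1p2k2, 2 for eATP against L-Glu in Col-0, 2 in glr3.3glr3.6 and 0 for p2k1p2k2 mock, in a fit with fewer libraries. Without 1 library, treatment, eATP against L-Glu and response counts lay between 0 and 1, shared calls between 0 and 1, glr3.3glr3.6 mock between 7 and 9, and p2k1p2k2 mock between 2 and 5 (2 without Col-0 mock 1 or 3). List calls (56) became 89 with the block within genotype, 87 with the block across genotypes and 0 with an estimated correlation, and lay between 49 and 72 without 1 library. Of the 56, quantile normalization lost 17 and reversed 2, no filter 18, median-of-ratios scaling 10, library weights 7, the mean of 5 FPKM 5, only the libraries compared 4, the block within genotype 1 and the pseudocount of 0.1 none. Averaged over treatments, glr3.3glr3.6 minus Col-0 called 25 genes, which became 394 with the block within genotype, 381 across genotypes and 41 with library weights, and 17 to 39 without 1 library (39 without Col-0 mock 3). For p2k1p2k2 minus Col-0 the 18 became 11 at a mean of 5 FPKM, 32 with median-of-ratios scaling, 1156 and 1098 with the blocks, 157 with library weights and 10 with only the libraries compared, and 13 to 101 without 1 library (101 without Col-0 mock 3, 91 without Col-0 eATP 2, 28 without Col-0 eATP 3 or p2k1p2k2 mock 2). Averaged eATP and L-Glu effects called 0 to 1 genes without 1 library. Directions that reversed were those of P2K2 in glr3.3glr3.6 mock (0.05 with library weights, 0.06 without Col-0 mock 2, -0.17 to 0.06 without 1 library), GLR3.3 in p2k1p2k2 mock (-0.03 without Col-0 mock 3, up to 0.09) and GLR3.6 there (-0.01 without p2k1p2k2 mock 3, up to 0.23), none of them called. The photosynthesis test reversed with quantile normalization for L-Glu in glr3.3glr3.6 (median -0.01) and eATP against L-Glu in Col-0 (-0.02), and the jasmonate test for eATP against L-Glu in p2k1p2k2 (0.11 without eATP 3, 0.11 without L-Glu 1, -0.51 to 0.11 without 1 library) and the L-Glu response of p2k1p2k2 (-0.08 without mock 1, -0.71 to -0.08 without 1 library). Genes called in Col-0 were too few to follow in the mutants. Depth limits are unknown, as FPKM carry no counts.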

Other observations

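The averaged effects, the tests of explanations and the tests of other splits in this part were all chosen after the data were seen. Averaged over the 3 treatments, libraries labelled glr3.3glr3.6 differed from Col-0 in 25 genes (13 higher, 12 lower, limma, n = 9 per genotype). Lower genes included SRC2, a cold-related membrane protein (388 ± 61.3 against 628 ± 126 FPKM, adjusted p = 0.00977), the dehydrin ERD10 (276 ± 43.4 against 411 ± 73.5 FPKM, adjusted p = 0.0191) and the kinase CIPK9 (-0.62, adjusted p = 0.0284). MYB51, a regulator of indole glucosinolates, was higher (176 ± 33.3 against 118 ± 24 FPKM, adjusted p = 0.03), and so was GLR3.3 (0.71, adjusted p = 1.51e-06). Abscisate, drought and cold genes were lower as a list (median -0.20, adjusted p = 0.00124, adjusted p = 0.265 with an estimated correlation) and so were heat shock genes (-0.30, adjusted p = 0.00124, adjusted p = 0.421 with an estimated correlation). Also called were salicylate (0.21, adjusted p = 0.0176, adjusted p = 0.981 with an estimated correlation) and receptors (0.03, adjusted p = 0.00185, adjusted p = 0.265 with an estimated correlation), higher, and photosynthesis (-0.04, adjusted p = 0.00185, adjusted p = 0.965 with an estimated correlation), lower. In other splits that exchanged genotypes within treatments but ignored the replicate number, 2 of 100 called as many genes, the real one included (337 at most). With the number as a block the count was 381 (147 higher, 234 lower, the 25 among them). In splits within treatment and number, 2 of 100 called as many with the block (385 at most), so chance is not excluded, as given below for p2k1p2k2. Calls rose to 39 without Col-0 mock 3.

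Libraries labelled p2k1p2k2 differed from Col-0 in 18 genes (11 higher, 7 lower), and in 1098 with the number as a block (669 higher, 429 lower, the 18 among them). Lower genes included XTH19 (0.975 ± 0.706 against 7.25 ± 5.79 FPKM, adjusted p = 0.0366), DWF4 (3.16 ± 0.591 against 5.13 ± 1.23 FPKM, adjusted p = 0.015) and BPS1 (125 ± 12.9 against 168 ± 14.4 FPKM, adjusted p = 0.00652). QQS was higher (59.2 ± 15.9 against 9.92 ± 1.93 FPKM), and so were ORTHL and LBD26 (0.94, adjusted p = 0.000122). ROS and high-light genes were lower as a list (median -0.17, adjusted p = 6.8e-06, adjusted p = 0.08 with an estimated correlation), as were calcium and touch genes (-0.14, adjusted p = 0.00733, adjusted p = 0.425 with an estimated correlation), evening clock genes (-0.10, adjusted p = 0.0326, adjusted p = 0.288 with an estimated correlation) and abscisate, drought and cold genes (-0.11, adjusted p = 0.0431, adjusted p = 0.425 with an estimated correlation). Epidermis markers (0.22, adjusted p = 0.0138, adjusted p = 0.395 with an estimated correlation) and receptors (0.09, adjusted p = 0.00342, adjusted p = 0.18 with an estimated correlation) were higher. The cell wall and growth list was not called (-0.03, adjusted p = 0.0814). In other splits that ignored the number, 4 of 100 called as many genes, the real one included, and 1 of them called 2318, which points to a structure of the libraries other than genotype. In splits within treatment and number, 1 of 100 (the real one) called as many as 1098 with the block (654 at most in the others). As for glr3.3glr3.6, these splits do not cover a difference shared by the libraries of 1 genotype and number, so chance is not excluded. Calls rose to 101 at most without 1 library. Averaged over genotypes, limma called 0 genes for eATP (263 at an unadjusted p under 0.05, 1053 with the number as a block) and 0 for L-Glu (176, 663 with the block), with and without the block, where chance alone gives 829, and salicylate genes were higher in both (0.25, adjusted p = 0.00146, adjusted p = 0.681 with an estimated correlation, and 0.24, adjusted p = 0.00182, adjusted p = 0.873 with an estimated correlation). Photosynthesis genes were lower in both (-0.03, adjusted p = 0.0148, adjusted p = 0.681 with an estimated correlation, and -0.03, adjusted p = 0.000982, adjusted p = 0.873 with an estimated correlation). Vascular markers were lower for eATP (-0.09, adjusted p = 0.0135, adjusted p = 0.51 with an estimated correlation) and ROS genes for L-Glu (median 0.00, adjusted p = 0.0394, adjusted p = 0.873 with an estimated correlation).

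All 4 genes for which the mutants are named stood higher in their own line. A library exchanged between genotypes would put a value on the other side of the gap in GLR3.6 or P2K2, and 0 libraries were there. Transcription that runs from an insertion into the next gene may contribute for the GLR genes: of 4 tested neighbours, 2 were called higher over the 3 treatments, TMT3 beside GLR3.6 (4.91 ± 0.15, adjusted p = 6.25e-16) and PMI1 beside GLR3.3 (1.15 ± 0.11, adjusted p = 1.51e-06). For the P2K genes 0 of 4 neighbours were called (AT3G45420 0.38, adjusted p = 0.145; AT5G60280 0.27, adjusted p = 0.305), which decides nothing, as such transcription need not reach a neighbour. Which exons were read was not analysed here, so a partial or chimeric transcript stays open for all 4. No test here showed that the whole lines carry the alleles their labels name, or that these remove the gene products, so a wrong label or allele for a whole line stays open too, and with it what each mutant comparison means. No biological explanation was tested.

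Replicate numbers differed more than any treatment: 8574 genes differed between numbers 2 and 1 (5306 higher, 3268 lower, 411 of them at least 2-fold) and 7110 between 3 and 1. Against number 1, early immune genes stood at -0.39 and -0.29, calcium and touch genes at -0.32 and -0.39 and ROS genes at -0.38 and -0.25 in numbers 2 and 3, and these calls held with an estimated correlation (adjusted p = 0.0073 to 0.042). Scaling between libraries is argued against, as 8295 genes were called after quantile normalization, 7780 of them among the 8574, and so is 1 odd library, as at least 7933 were called without any one. A different hour of harvest might fit the morning clock list (median -0.49 in number 2, adjusted p = 0.000615, adjusted p = 0.188 with an estimated correlation) but the evening clock list stood at -0.01, and members move both ways, so it stays open with growth, handling and sequencing batch, which the labels do not give. With numbers reassigned within groups, 1 of 100 splits (the real one) called as many genes (3662 at most in the others), so chance is excluded.

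Splits of 3 against 3 libraries give 10 groupings and never a share under 0.1. For genes, a real count of 0 for each comparison with mock and for eATP against L-Glu makes all 10 splits as large whatever the data, which tests nothing (at most 1 gene in the others), while glr3.3glr3.6 mock called 8 and p2k1p2k2 mock 6 with 0 at most in the other splits, so that 1 of 10 was as large. For lists, adjusted within the comparison, the real and highest other counts after eATP were 2 and 10 in Col-0 (8 of 10 splits as large), 8 and 9 in glr3.3glr3.6 (4) and 4 and 13 in p2k1p2k2 (7). After L-Glu they were 1 and 8 in Col-0 (9), 4 and 11 in glr3.3glr3.6 (8) and 4 and 11 in p2k1p2k2 (6). For eATP against L-Glu they were 7 and 6 in Col-0 (1), 2 and 10 in glr3.3glr3.6 (8) and 3 and 11 in p2k1p2k2 (8), and for the mocks 4 and 8 in glr3.3glr3.6 (7) and 3 and 11 in p2k1p2k2 (5). In the comparisons whose numbers pair the libraries, splits that part all 3 pairs, as the real one does, called at most 3 lists for eATP and 2 for L-Glu in p2k1p2k2, 2 for L-Glu in Col-0, 6 for L-Glu in glr3.3glr3.6, 2, 2 and 5 for eATP against L-Glu in Col-0, glr3.3glr3.6 and p2k1p2k2, and 2 for p2k1p2k2 mock. Splits that keep a number on one side called up to 13, 11, 8, 11, 6, 10, 11 and 11 in the same order, so the highest other counts follow the replicate number.

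MT1A was at 110 and 39.1 FPKM in p2k1p2k2 mock 2 and 3 and at most 0.111 in the other libraries, and PR1 was lower in numbers 2 and 3 than in number 1 by 2.54 and 4.44 on the log2 scale (adjusted p = 0.00383 and 4.67e-05).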
